A study of Mus musculus with 8 samples.

How the data were processed

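RNA of 8 samples of mouse ES cells was profiled on 1 array each: 3 with a control hairpin against GFP, 3 with a hairpin against Jmjd2b and 2 with a hairpin against Jmjd2c. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says whether replicates came from separate infections or cultures, so p-values measure the spread between these samples, which may be technical. Per the labels' protocols, total RNA was labelled as biotinylated cRNA by the array maker's standard method. The deposited values are intensities on a linear scale, 1 per probe set. How the authors summarised probes, corrected the background and scaled the arrays is not given in the sources used here. The array medians, between 44.7 and 46.6, show that some scaling between arrays had been applied, and its kind stays unknown.

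The deposited intensities differed between arrays at their low end. In control arrays 1 and 2 and Jmjd2b knockdown array 2, between 412 and 455 values were exactly 1 and at most 2 were lower, while in the other 5 arrays between 172 and 241 values lay below 1. This array type was added as a block in an alternative chosen after seeing the data, and the groups were also compared within each type. Between 23.9% and 25.4% of the probe sets of each array had a value under 16. Ratios of 3' to 5' probe sets, which rise with RNA degradation, lay between 1.31 and 1.63 for actin and between 0.936 and 0.987 for Gapdh. The actin ratio moved with the group: it was 1.63, 1.45 and 1.56 in the controls, 1.42, 1.36 and 1.31 in the Jmjd2b knockdown and 1.48 and 1.43 in the Jmjd2c knockdown. No pair of arrays shared more than 0.621% of its values exactly, so none was counted as a repeat of another. Identical values also marked out sets among the 5 arrays without the floor at 1. Jmjd2b knockdown array 3 and both Jmjd2c knockdown arrays shared 0.599% to 0.621% with each other. Control array 3 and Jmjd2b knockdown array 1 shared 0.459%. Pairs across these sets shared 0.0488% to 0.0798%, for a cause that is unknown. Array type did not part these sets. No control lay in the set of the Jmjd2c knockdown arrays, so their comparison with controls crossed sets.

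Probe sets were named from the platform annotation of the array, which gave exactly 1 gene symbol for 34945 of 45101 probe sets, several for 932 and no listed symbol for 9160; 64 were array controls. Gene identifiers of 34741 probe sets matched a RefSeq gene table (GRCm38.p6), used for names and chromosome membership only, and 0 symbols needed an update. Values were converted to log2(value + 16), which understates changes of dim genes, and every fold is on that scale. Each of 18193 genes was represented by its probe set with the highest mean over all arrays. The columns were not normalized further and dim genes were not removed. Among 195 called results of named genes against the control, 73 had more than 1 probe set above the median level, and 0 of those had such a probe set moving the opposite way.

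Group means were fitted to all 8 arrays in 1 model in limma 3.58.1 (R 4.3.3) with lmFit and eBayes with a trend, so that the group of 2 arrays shares the estimate of spread with the others. Tests were two-sided and adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. The 26 gene lists, of which 484 of 524 entries were measured, were tested with camera at a preset correlation of 0.01, with adjustment over the 26 lists of a comparison. With an estimated correlation camera called 0 lists in each comparison (the lowest adjusted p was 0.194, 0.217 and 0.187, and 5, 3 and 4 lists had an unadjusted p under 0.05). The overlap of calls and the correlation of changes were set beside 100 simulations of unchanged groups against the same controls. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

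The design, the gene lists, the alternatives apart from array type, and the rule for named genes were fixed before the data were examined. The rule names the 4 KDM4 genes; for each knockdown the 10 largest rises and 10 largest falls among called genes whose knockdown arrays all lie on 1 side of all control arrays and whose higher group mean exceeds the median of all genes; 5 each way between the knockdowns; 5 shared genes each way; and up to 4 members of each list with the smallest p. Genes known only by clone or predicted-gene names were passed over. Some named list members are given by value alone where they did not pass.

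Whether replicate numbers pair the arrays was checked by the deviations of arrays from their group means. For same-numbered control and Jmjd2b knockdown arrays these correlated at 0.176, 0.111 and 0.116 across genes. For differently numbered ones they correlated at -0.127 to 0.0164. Groups of 3 arrays are too small for these values to establish a pairing, and the labels state none. For the Jmjd2c knockdown, with 2 arrays, the correlations with same-numbered controls were 0.0422 and 0.0640 and with Jmjd2b knockdown arrays -0.0596 and 0.141. Differently numbered Jmjd2b and Jmjd2c knockdown arrays correlated at -0.166 to 0.166. Alternatives were the replicate block, pseudocounts of 1 and 64, quantile normalization, centring on array medians, only the brighter genes, the mean of all probe sets of a gene, leaving out probe sets prone to cross-hybridisation, no variance trend, only the 2 groups compared in the fit, a 2-fold minimum, an estimated correlation for the lists, array type as a block, and leaving out each array in turn. Where leaving out an array, or keeping 1 array type, left a group with 1 array, the lone array was assumed to vary like the other groups in that fit.

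The fit was tested on simulated data for 18193 genes with known changes. The changed genes were all drawn from those above the median control level, so recovery of dim genes was not measured. Noise was drawn independently for each gene with the same spread in all groups, so a larger spread in 1 group was not covered. For the Jmjd2b comparison the fit recovered 20.9%, 91.0% and 100% of the 67, 67 and 66 genes with log2 changes of 0.5, 1 and 2, with 10 false calls among 151 (6.62%). For the Jmjd2c comparison it recovered 20.9%, 85.1% and 100%, with 8 false calls among 145 (5.52%). In the simulated Jmjd2b comparison the list that was shifted was called, as was 1 of the others among the 26 lists run. Simulated genes varied independently, so this run cannot test the preset correlation of 0.01 for lists whose members vary together. Probe sets without a single gene symbol were left out of the gene tests.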

Results

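Transcript levels were measured on 8 oligonucleotide arrays, 1 array per sample, in male mouse embryonic stem (ES) cells of strain 129S4/Svjae kept in medium with leukemia inhibitory factor (LIF). ES cells are cultured cells of the early embryo that can form all tissues of the body. The cells received lentiviral short hairpin RNAs against GFP (3 control samples), against Jmjd2b (3 samples) or against Jmjd2c (2 samples), were selected with puromycin, and were passaged before RNA was taken. Jmjd2b and Jmjd2c, listed on the array as Kdm4b and Kdm4c, are histone demethylases that act on lysine 9 and lysine 36 of histone H3. The question named by the study's title is the role of both enzymes in ES cell identity. The probe sets of each array had intensities between 0.19 and 18574, and the array medians lay between 44.7 and 46.6. After conversion to log2, arrays of 1 group correlated at 0.981 to 0.993 across all probe sets and arrays of different groups at 0.963 to 0.985. The lowest value within a group, 0.981, was that of the 2 Jmjd2c knockdown arrays. Each of them correlated more closely with Jmjd2b knockdown array 1 (0.985 for both) than with its replicate. Jmjd2c knockdown array 1 also correlated more closely with control array 2 (0.984) than with its replicate. The number of arrays limits the precision of every value, and the Jmjd2c knockdown had only 2.

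The transcript targeted by each hairpin was lower in the arrays of that hairpin than in the controls. Kdm4b had an intensity of 468 ± 157 (SD, n = 3) in the control and 32.2 ± 16.8 (SD, n = 3) in the Jmjd2b knockdown, which is 6.89% of the control mean. The 3 knockdown arrays lay at 10.8%, 6.27% and 3.64%. Its log2 change was -3.34 ± 0.28 (SE; limma, adjusted p = 7.79e-05). Kdm4c had 1281 ± 63.2 (SD, n = 3) in the control and 306 ± 232 (SD, n = 2) in the Jmjd2c knockdown, or 23.9% of the control mean. The 2 Jmjd2c knockdown arrays differed, at 11.1% and 36.7% of it, and the log2 change was -2.23 ± 0.36 (SE; limma, adjusted p = 0.0069). Without the first of these arrays the change was -1.42, and without the second it was -3.04. Each knockdown also had a lower mean for the other target that did not pass the test. Kdm4c stood at 57.3% of the control mean in the Jmjd2b knockdown (limma, adjusted p = 0.10) and Kdm4b at 56.6% in the Jmjd2c knockdown (adjusted p = 0.18). Kdm4a, another family member, fell in the Jmjd2b knockdown by 0.80 ± 0.12 on the log2 scale (SE; limma, adjusted p = 0.0011) and had a value of -0.22 ± 0.13 in the Jmjd2c knockdown (adjusted p = 0.355). With the mean of its probe sets, of which 1 is dim, the value in the Jmjd2b knockdown was -0.39 and did not pass, and that in the Jmjd2c knockdown was 0.15. With only those 2 groups in the fit Kdm4c passed in the Jmjd2b knockdown. Kdm4d had mean intensities between 14.5 and 18.8 in the 3 groups, near the floor of the array, and passed no test.

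**Figure D1:**
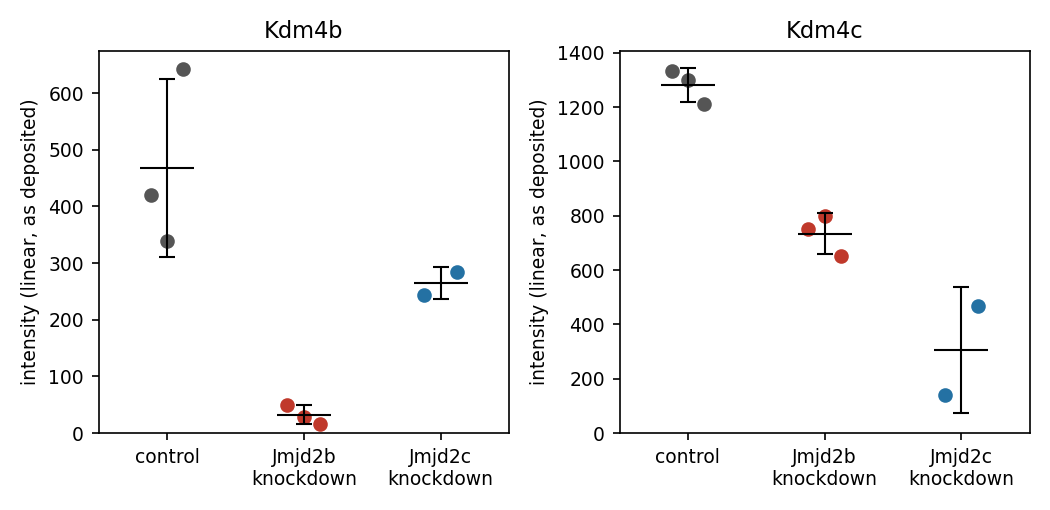
Deposited linear intensity (y axis) of Kdm4b (left) and Kdm4c (right) in each array of the control, the Jmjd2b knockdown and the Jmjd2c knockdown (x axis). Points are arrays, the long horizontal line is the group mean and the bars are ± 1 SD, and Kdm4b fell to 6.89% of the control mean in the Jmjd2b knockdown and Kdm4c to 23.9% in the Jmjd2c knockdown.

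The first comparison asked which transcripts changed when Jmjd2b was knocked down. Genes of naive pluripotency, the ground state of ES cells, fell, and genes of the primed epiblast, the later pluripotent tissue of the implanted embryo, rose. Of 20 naive pluripotency genes, 17 fell and 1, Gbx2 (log2 change 1.09, named after its value was seen), rose, with a median of -0.74 (camera, adjusted p = 4.56e-09, and adjusted p = 0.194 with an estimated correlation). Klf4, a transcription factor of the naive state, fell from an intensity of 6357 ± 419 to 2182 ± 324 (SD, n = 3 each; log2 change -1.54 ± 0.10, SE). Esrrb, a nuclear receptor, changed by -1.53 ± 0.12, the 5-methylcytosine oxidase Tet2 by -2.09 ± 0.18 and Prdm14 by -1.74 ± 0.17. Of 15 primed epiblast genes, 13 rose and 0 fell, with a median of 1.51 (camera, adjusted p = 2.02e-10, and adjusted p = 0.194 with an estimated correlation). Fgf5, a growth factor of the primed epiblast, rose from 9.26 ± 7.27 to 1330 ± 595 (log2 change 5.67 ± 0.35, a size that depends on the pseudocount because the control lies below it). The adhesion gene Cdh2 rose by 3.68 ± 0.16, Zic2 by 2.22 ± 0.20 and Krt18 by 2.18 ± 0.25. In every called gene that the rule for named genes takes, all arrays of the knockdown lay on 1 side of all arrays of the group it was compared with. The rule itself requires this of the largest rises and falls, and takes list members by their smallest p. This separation is therefore no further support. Adjusted over the list alone, the counts were again 17 and 1 for the naive list and 13 and 0 for the primed list.

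The general pluripotency list did not move as a whole in the Jmjd2b knockdown: 5 of its 17 measured genes rose, 3 fell, and the same numbers passed adjusted over the list alone (camera, adjusted p = 0.150). Pou5f1, Sox2 and Nanog were looked up as a set after the values were seen. Pou5f1 (Oct4) had 7829 ± 43.0 in the control and 7821 ± 202 in the knockdown (SD, n = 3 each; limma, adjusted p = 0.98). Sox2 changed by -0.25 ± 0.04 (SE; adjusted p = 0.0032) and Nanog, a member of the naive list, by -0.67 ± 0.14 (adjusted p = 0.0059). Lin28a rose by 0.87 ± 0.19, Sall4 rose by 0.33 ± 0.09, and Tet1 fell by 0.60 ± 0.11.

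Of 18 neural ectoderm genes, 7 rose and 0 fell in the Jmjd2b knockdown, against 7 and 1 adjusted over the list alone (median 0.27, camera, adjusted p = 0.0016, and adjusted p = 0.234 with an estimated correlation). They included the neurofilament genes Nefl (3.09 ± 0.16, SE) and Nefm (4.59 ± 0.28), Zic1 (1.72 ± 0.19) and Nes (1.57 ± 0.18). Of 19 genes of mesoderm and primitive streak, 6 rose and 1 fell, and 6 and 2 passed adjusted over the list alone (camera, adjusted p = 0.032, and adjusted p = 0.373 with an estimated correlation). Fgf8 changed by 4.14 ± 0.25, Wnt3 by 2.31 ± 0.19, Evx1 by 2.70 ± 0.32 and Eomes by 2.12 ± 0.31. With only the brighter genes the median of this list turned from 0.16 to -0.85. Its call was also lost with only the 2 groups in the fit and without control array 2, Jmjd2b knockdown array 2 or either Jmjd2c knockdown array. The median was 0.01 without control array 2, and 0.28 and 0.11 without Jmjd2b knockdown arrays 1 and 3. The lists of primitive endoderm (6 rose and 2 fell of 22, 7 and 2 adjusted over the list alone, camera, adjusted p = 0.093) and trophectoderm (4 and 5 of 18, with 4 and 5 adjusted over the list alone; adjusted p = 0.924) were not called. Within them Fst, which binds activin, changed by 4.42 ± 0.41, Cited1 by 2.11 ± 0.23, Dab2 by 1.35 ± 0.16 and Sparc by 0.86 ± 0.11. Cdx2, a transcription factor of trophectoderm and of the posterior embryo, rose from 4.24 ± 2.69 to 442 ± 102 (SD, n = 3 each), Krt8 rose by 2.55 ± 0.26, and Tead4 (-0.93 ± 0.22) and Tfap2c (-0.44 ± 0.11) fell. For fibroblast markers, which would mark feeder cells, 6 of 21 rose and 3 fell, and 7 and 4 passed adjusted over the list alone (camera, adjusted p = 0.102). Tagln, an actin-binding protein of smooth muscle, changed by 4.90 ± 0.50, the collagen gene Col1a1 by 1.34 ± 0.17 and Pdgfrb by -1.36 ± 0.21. The value of Acta2, 1.43 ± 0.12, is uncertain, since its probe set can detect related genes, and without such probe sets, on a dim one, the value was -0.02.

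Of 20 Wnt pathway genes 7 rose and 2 fell, the same adjusted over the list alone (camera, adjusted p = 0.0039, and adjusted p = 0.237 with an estimated correlation). The Wnt target Sp5 changed by 4.74 ± 0.31, Wnt4 by 2.19 ± 0.17 and the receptor Fzd5 by -1.09 ± 0.10. The call of the Wnt list was lost with only the brighter genes. Of 20 genes of the TGF-beta, Nodal and BMP pathway 10 rose and 1 fell, or 11 and 2 adjusted over the list alone (camera, adjusted p = 0.011, and adjusted p = 0.237 with an estimated correlation). Inhbb fell by 2.59 ± 0.25, Id3 rose by 1.56 ± 0.19, Nodal by 1.18 ± 0.15 and Smad1 by 0.52 ± 0.13. Of 20 imprinted genes, which are read from 1 parental copy, 12 rose and 2 fell (14 and 2 adjusted over the list alone; median 0.77, camera, adjusted p = 5.64e-05, and adjusted p = 0.194 with an estimated correlation). Plagl1 changed by 3.44 ± 0.64, Peg3 by 1.42 ± 0.16, Meg3 by 1.41 ± 0.15 and Ndn by 1.41 ± 0.24. In the interferon response list 9 of 22 rose and 3 fell, the same adjusted over the list alone (camera, adjusted p = 0.032, and adjusted p = 0.237 with an estimated correlation). Gbp2 changed by 4.66 ± 0.38, Psmb8 by 3.50 ± 0.41, Oasl2 by 2.31 ± 0.25 and Irf1 by 1.57 ± 0.15. This call was lost without Jmjd2b knockdown array 2, where the median went from 0.15 to 0.08. Of 20 p53 target genes 7 rose and 1 fell (9 and 1 adjusted over the list alone, camera, adjusted p = 0.0032, and adjusted p = 0.360 with an estimated correlation). Perp changed by 2.01 ± 0.26, Tap1 by 1.27 ± 0.17 and Plk2 by 1.23 ± 0.15.

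Of 23 genes of glycolysis and the hypoxia response 15 fell and 0 rose, or 18 and 0 adjusted over the list alone (median -0.50, camera, adjusted p = 4.56e-09, and adjusted p = 0.194 with an estimated correlation). Vegfa, a growth factor of blood vessels, changed by -1.72 ± 0.13, Ankrd37 by -1.71 ± 0.16, hexokinase Hk1 by -1.88 ± 0.20 and Ndrg1 by -2.31 ± 0.25. Of 19 genes of the unfolded protein and amino acid stress responses 9 fell and 1, Hspa5 (0.49, named after its value was seen), rose, against 11 and 2 adjusted over the list alone (camera, adjusted p = 0.0033, and adjusted p = 0.237 with an estimated correlation). Nupr1, a stress-induced gene, fell from 1065 ± 195 to 57.9 ± 37.8 (SD, n = 3 each), and Ddit3 fell by 2.47 ± 0.34. Chac1 changed by -1.85 ± 0.23 and Trib3 by -1.39 ± 0.21. Of 20 genes of G2 and mitosis 11 fell and 0 rose, the same adjusted over the list alone, by small amounts (median -0.28, camera, adjusted p = 2.13e-04, and adjusted p = 0.360 with an estimated correlation). Nusap1 changed by -0.74 ± 0.07, Tpx2 by -0.55 ± 0.10, Bub1 by -0.52 ± 0.09 and Bub1b by -0.49 ± 0.08. The lists of G1, S phase and replication (6 fell and 1 rose of 20, 7 and 1 adjusted over the list alone, camera, adjusted p = 0.032, and adjusted p = 0.377 with an estimated correlation) and of germline genes (6 fell and 0 rose of 20, the same adjusted over the list alone, camera, adjusted p = 0.032, and adjusted p = 0.574 with an estimated correlation) were called near the threshold. Both calls were lost with only the 2 groups in the fit and without Jmjd2b knockdown array 2 or either Jmjd2c knockdown array. The germline call was also lost with only the brighter genes and without control array 1 or Jmjd2b knockdown array 1, and the G1 and S phase call without control array 2. The germline median went from -0.32 to -0.16 without control array 1 and to -0.55 without Jmjd2b knockdown array 3. Rrm2 changed by -0.46 ± 0.05, E2f1 by -0.85 ± 0.17, Ccnd3 by -0.55 ± 0.10 and Ccnd1 by 0.80 ± 0.13. The meiosis genes changed too, Smc1b by -2.35 ± 0.28, Stra8 by -2.28 ± 0.27, Sycp3 by -1.49 ± 0.27 and Hormad1 by -1.40 ± 0.21.

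**Figure D2:**
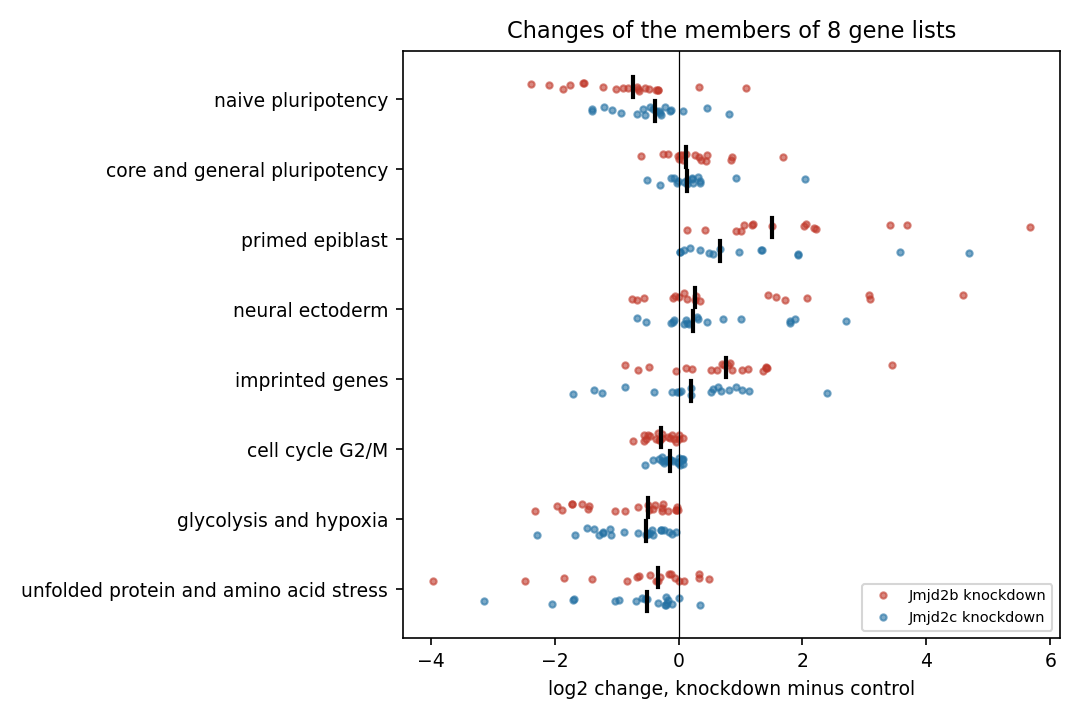
Log2 change against control (x axis) of each measured member of 8 gene lists (y axis) in the Jmjd2b knockdown (red) and the Jmjd2c knockdown (blue), with the median of each list as a black bar and random vertical scatter. The naive pluripotency list has its medians at -0.74 and -0.38, the primed epiblast list at 1.51 and 0.67 and the glycolysis and hypoxia list at -0.50 and -0.53.

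Lists of chromatin genes were not called in the Jmjd2b knockdown, apart from the KDM4 family of 4 genes that holds the target (2 fell, 3 adjusted over the list alone, camera, adjusted p = 0.011, and adjusted p = 0.215 with an estimated correlation). For Polycomb complex members 3 of 20 rose and 4 fell, the same adjusted over the list alone (adjusted p = 0.884), with Rbbp7 at 0.40 ± 0.06, Ezh2 at -0.46 ± 0.07, Kdm2b at 0.60 ± 0.10 and Ezh1 at -1.10 ± 0.21. For enzymes and readers of H3 lysine 9 methylation and heterochromatin 4 of 18 rose and 4 fell, or 5 and 5 adjusted over the list alone (adjusted p = 0.952), with Uhrf1 at -0.43 ± 0.09, Atrx at 0.44 ± 0.10, Ehmt1 at 0.47 ± 0.10 and Kdm3b at -0.49 ± 0.11. Of 31 Hox genes 1 (Hoxd13, 0.89 ± 0.21) rose and 1 (Hoxc4, -0.48 ± 0.16) fell, and 0 passed adjusted over the list alone (adjusted p = 0.924). Of 8 measured genes of the 2-cell-like state 0 passed the test over all genes or adjusted over the list alone (adjusted p = 0.709). Lists of apoptosis regulators (6 rose and 2 fell of 14, 8 and 3 adjusted over the list alone; adjusted p = 0.055), immediate early genes (5 and 2 of 17, 6 and 2 adjusted over the list alone; adjusted p = 0.094) and cholesterol synthesis (6 and 0 of 18, the same adjusted over the list alone; adjusted p = 0.162) were not called either. Bcl2 changed by 1.37 ± 0.19, Bcl2l1 by 0.88 ± 0.13, Birc2 by -0.84 ± 0.13, Myc by 1.36 ± 0.25, Ier3 by -1.19 ± 0.23 and Idi1 by 0.61 ± 0.11.

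Across all 18193 genes, 4441 passed the test in the Jmjd2b knockdown, 2097 up and 2344 down (limma, adjusted p under 0.05), and 1166 of them changed at least 2-fold. Among genes with all 3 knockdown arrays on the same side of all 3 control arrays, which chance gives in 10% of genes, and above the median level, the largest rises were those of Fgf5, Gbp2b (5.29 ± 0.60), Igfbp3 (5.06 ± 0.35), Tagln, Sp5, the myosin light chain Myl9 (4.73 ± 0.47), Gbp2, Nefm, Cdx2 and Fst. The largest falls were those of Nupr1 (-3.97 ± 0.43), Lrrc31 (-3.40 ± 0.30), Kdm4b, the metal transporter Slc11a1 (-3.20 ± 0.22), Camk2n1 (-3.17 ± 0.33), Fam183b (-2.84 ± 0.26), Ampd3 (-2.83 ± 0.23), the glycogen phosphorylase Pygl (-2.79 ± 0.29), Kdelr3 (-2.75 ± 0.29) and Pde8a (-2.73 ± 0.32). Gbp2 and Gbp2b are close relatives whose signals may not be separable. In 3 arrays (2 controls and 1 Jmjd2b knockdown array) between 412 and 455 values were exactly 1 and at most 2 were lower, while in the other 5 between 172 and 241 values lay below 1. With that array type as a block 3888 genes were called and every list called above was called again by camera. Within the first type (2 controls, 1 knockdown array) 1138 genes were called and within the second (1 control, 2 knockdown arrays) 99, counts that take the spread of the lone array from the other groups of that type. The list medians within the types were -0.78 and -0.85 for naive genes, 1.51 and 1.65 for primed genes, -0.64 and -0.53 for glycolysis and hypoxia, -0.43 and -0.29 for the stress responses and 0.82 and 0.61 for imprinted genes. For germline genes they were -0.55 and -0.04, for the interferon list 0.34 and 0.06, and for mesoderm genes 0.30 and 0.08. The others were 0.25 and 0.44 (neural), 0.52 and 0.32 (TGF-beta, Nodal and BMP), 0.51 and 0.31 (Wnt), 0.21 and 0.30 (p53), -0.33 and -0.29 (G2 and mitosis), -0.16 and -0.15 (G1, S phase and replication) and -0.68 and -0.87 (KDM4 family). The 3' to 5' ratio of actin probe sets, a sign of RNA quality, was higher in all 3 controls (1.45 to 1.63) than in all 3 Jmjd2b knockdown arrays (1.31 to 1.42). The count was 2624 without control array 3 and 2747 without Jmjd2b knockdown array 2. It was 5612 with only the 2 groups in the fit, where the spread of the Jmjd2c knockdown arrays does not enter.

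The second comparison asked the same of Jmjd2c. The naive pluripotency and primed epiblast lists moved in the direction they had in the Jmjd2b knockdown, with smaller median changes. The knockdowns differed in depth, with Kdm4b at 6.89% and Kdm4c at 23.9% of the control mean. Neither these sizes nor the differences between the knockdowns given below were measured at equal depth. Of 20 naive pluripotency genes 8 fell and 0 rose, or 11 and 0 adjusted over the list alone (median -0.38, camera, adjusted p = 1.48e-05, and adjusted p = 0.298 with an estimated correlation). Klf4 changed by -1.20 ± 0.11 (SE), Tet2 by -1.40 ± 0.20, Esrrb by -0.93 ± 0.13 and the T-box factor Tbx3 by -1.40 ± 0.27. Nanog (-0.41 ± 0.15; limma, adjusted p = 0.13), Sox2 (-0.12 ± 0.05; adjusted p = 0.16) and Pou5f1 (-0.07 ± 0.05; adjusted p = 0.48), looked up after the values were seen, did not pass. Of 15 primed epiblast genes 6 rose and 0 fell, or 7 and 0 adjusted over the list alone (median 0.67, camera, adjusted p = 3.80e-07, and adjusted p = 0.318 with an estimated correlation). Fgf5 rose by 4.69 ± 0.39 (with the same dependence on the pseudocount), Cdh2 by 3.58 ± 0.18, Zic2 by 1.93 ± 0.23 and the homeobox gene Otx2 by 1.34 ± 0.20. Without Jmjd2c knockdown array 2 the primed median was 1.29. Of 17 general pluripotency genes 2 fell, Tdgf1 (-0.29 ± 0.06) and Tet1 (-0.50 ± 0.12), and 2 rose and 2 fell adjusted over the list alone (camera, adjusted p = 0.260).

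The list with the smallest p in the Jmjd2c knockdown was that of glycolysis and hypoxia, in which 16 of 23 genes fell and 0 rose, or 21 and 0 adjusted over the list alone (median -0.53, camera, adjusted p = 2.29e-14, and adjusted p = 0.217 with an estimated correlation). Bnip3 changed by -1.68 ± 0.19, Vegfa by -1.28 ± 0.15, Ndrg1 by -2.28 ± 0.27 and Ankrd37 by -1.47 ± 0.18. Of 19 genes of the unfolded protein and amino acid stress responses 10 fell and 0 rose, or 11 and 0 adjusted over the list alone (median -0.51, camera, adjusted p = 5.38e-07, and adjusted p = 0.217 with an estimated correlation). They included Atf4, the transcription factor of amino acid shortage (-0.58 ± 0.09), asparagine synthetase Asns (-0.96 ± 0.14), Chac1 (-2.04 ± 0.26) and Trib3 (-1.70 ± 0.23). Of 20 germline genes 3 fell and 0 rose (4 and 0 adjusted over the list alone, camera, adjusted p = 0.045, and adjusted p = 0.667 with an estimated correlation), which were Stra8 (-2.37 ± 0.30), Sycp3 (-1.57 ± 0.31) and Smc1b (-1.25 ± 0.31). This call was lost with the replicate block, with quantile normalization, with only the brighter genes and without control array 1 or either Jmjd2c knockdown array. Its median of -0.17 was -0.26 and -0.31 without Jmjd2c knockdown arrays 1 and 2.

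Of 18 neural ectoderm genes 4 rose and 0 fell in the Jmjd2c knockdown, against 5 and 1 adjusted over the list alone (camera, adjusted p = 0.0032, and adjusted p = 0.318 with an estimated correlation), namely Nefl (1.80 ± 0.18), Fabp7 (2.70 ± 0.43), Pax6 (1.88 ± 0.31) and Nefm (1.80 ± 0.31). That call was lost with only the brighter genes and without Jmjd2c knockdown array 1. The median of 0.23 was 0.15 without control array 3 and 0.43 without Jmjd2c knockdown array 2, and Fabp7 was at 1.78 without array 1. In the TGF-beta, Nodal and BMP pathway 6 of 20 genes rose and 2 fell (10 and 2 adjusted over the list alone, camera, adjusted p = 0.0073, and adjusted p = 0.320 with an estimated correlation), with Id3 at 1.40 ± 0.21, Id1 at 1.22 ± 0.27, Acvr2b at 0.69 ± 0.17 and Inhbb at -1.35 ± 0.28. Without Jmjd2c knockdown array 2 it was not called, and Id1 was at 0.76. In the Wnt pathway 5 of 20 rose and 1 fell (7 and 1 adjusted over the list alone, camera, adjusted p = 0.0073, and adjusted p = 0.340 with an estimated correlation), with Sp5 at 2.07 ± 0.35, Tcf7l1 at 1.11 ± 0.19, Wnt3 at 1.22 ± 0.21 and Fzd5 at -0.63 ± 0.11. The call was lost with only the brighter genes, and the median went from 0.22 to 0.14 without control array 2. Of 20 p53 target genes 2 rose, Perp (1.32 ± 0.30) and Plk2 (0.73 ± 0.17), and 3 adjusted over the list alone (camera, adjusted p = 0.041, and adjusted p = 0.596 with an estimated correlation). That call was lost with the array type as a block, with only the brighter genes and without control arrays 2 or 3 or Jmjd2c knockdown array 2. The median of 0.12 was 0.27 and 0.02 without Jmjd2c knockdown arrays 1 and 2, and Perp was at 0.70 without array 2.

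The other lists were not called in the Jmjd2c knockdown. Imprinted genes went both ways (4 rose and 3 fell of 20, 7 and 4 adjusted over the list alone, camera, adjusted p = 0.175), with Peg3 at 0.92 ± 0.18, Ndn at 1.13 ± 0.27, the cell cycle inhibitor Cdkn1c at -1.36 ± 0.29 and Ascl2 at -1.24 ± 0.27. Without Jmjd2c knockdown array 2 Cdkn1c was at -0.76 and Ndn at 0.53, and without array 1 Ndn was at 1.74. For other cell types, 3 of 22 primitive endoderm genes rose and 1 fell (3 and 3 adjusted over the list alone; adjusted p = 0.302), among them Fst (2.91 ± 0.46) and Amn (-0.82 ± 0.15), 3 of 19 mesoderm genes rose and 2 fell (4 and 3; adjusted p = 0.312), among them Fgf8 (2.65 ± 0.28), and 2 of 18 trophectoderm genes rose and 2 fell (5 and 4; adjusted p = 0.569), among them Cdx2 (0.97 ± 0.22) and Esx1 (-1.30 ± 0.16). Of 21 fibroblast markers 2 rose and 2 fell (2 and 3; adjusted p = 0.312), among them Tagln (3.14 ± 0.56) and Thy1 (-1.44 ± 0.27, and -0.92 without Jmjd2c knockdown array 2). In the interferon list 3 of 22 rose and 2 fell (4 and 3; adjusted p = 0.434), with Gbp2 at 3.57 ± 0.42 and Stat2 at -1.03 ± 0.17. The remaining counts, rises before falls and with those adjusted over the list alone after each, were 0 and 2 of 20 (0 and 2) for G2 and mitosis, 1 and 2 of 20 (1 and 4) for G1, S phase and replication, 3 and 1 of 14 (3 and 2) for apoptosis regulators, 0 and 2 of 17 (0 and 3) for immediate early genes and 1 and 1 of 20 (1 and 1) for Polycomb members. In the KDM4 family 1 gene of 4, the target, fell, also adjusted over the list alone. The adjusted p of these 6 lists by camera lay between 0.066 for the KDM4 family and 0.878 for the Polycomb members. For Hox genes, H3 lysine 9 methylation, the 2-cell-like state and cholesterol synthesis 0 genes passed over all genes or over the list alone (adjusted p of these lists by camera from 0.206 to 0.963).

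Across all genes, 1733 of 18193 passed in the Jmjd2c knockdown, 778 up and 955 down, and 553 changed at least 2-fold (limma). The rule for named genes was less strict here, since chance separates 2 knockdown arrays from 3 controls more often than 3 from 3. By the same rule as above the largest rises were those of Fgf5, the immunity GTPase Irgm1 (3.70 ± 0.33), Gbp2b (3.62 ± 0.67), Igfbp3 (3.60 ± 0.39), Cdh2, Gbp2, Myl9 (3.41 ± 0.53), cardiac actin Actc1 (3.38 ± 0.67), the ephrin Efnb2 (3.28 ± 0.43) and Fgfbp1 (3.23 ± 0.47). The largest falls were those of Nupr1 (-3.14 ± 0.48), the dynein gene Dnah8, transglutaminase Tgm2 (-2.81 ± 0.38), Slc11a1 (-2.71 ± 0.25), Kdelr3 (-2.70 ± 0.32), Camk2n1 (-2.64 ± 0.37), Lrrc31 (-2.46 ± 0.34), Stra8, Pde8a (-2.35 ± 0.36) and Ppp1r14d (-2.32 ± 0.29). Dnah8, at 162 and 4.06 in the 2 knockdown arrays, had log2 changes of -4.57 without the first and -1.43 without the second. The 2 arrays of this group also lay apart along the second principal component of the genes, at 16.4 and -38.7, which held 13.4% of the variance. The count was 462 without control array 3, 853 without control array 1, 2919 without Jmjd2c knockdown array 1, 874 with only the 2 groups in the fit and 1043 with array type as a block. Within the 1 array type that held Jmjd2c knockdown arrays there was 1 control, and limma, with the spread of that control taken from the knockdown groups, called 0 genes there (2176 at an unadjusted p under 0.05), with medians of -0.48 for the naive, 0.77 for the primed, -0.65 for the glycolysis and hypoxia and -0.53 for the stress list. The other called lists had medians there of 0.29 (neural), 0.37 (TGF-beta, Nodal and BMP), 0.19 (Wnt), 0.14 (p53) and -0.07 (germline). The control of that type, array 3, shared 0.0732% and 0.0621% of its values exactly with the Jmjd2c knockdown arrays. These shared 0.621% with each other, so the medians within the type still crossed the sets marked out by identical values. Calls were lost with array type as a block for Gbp2b, Tagln and Dnah8, without control array 1 for Actc1, Tbx3, Cdx2 and Dnah8, and without control array 3 for Tbx3, Cdx2 and Dnah8. The call of Cdx2 was also lost with the replicate block and without Jmjd2c knockdown array 1.

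The third comparison set the knockdowns against each other, since a gene called in 1 of them need not differ between them. Of 18193 genes 85 differed, 25 higher and 60 lower in the Jmjd2c knockdown (limma, adjusted p under 0.05), and 50 higher and 64 lower after quantile normalization. Kdm4b was higher in the Jmjd2c knockdown by 2.60 ± 0.31 (SE), followed by Phf11d (1.61 ± 0.21), Hormad1 (1.42 ± 0.23), As3mt (1.40 ± 0.23) and the naive pluripotency gene Prdm14 (1.39 ± 0.19). Cdx2 was lower by -3.52 ± 0.22, Nefm by -2.79 ± 0.31, Sp5 by -2.67 ± 0.35, Tmcc3 by -2.64 ± 0.41 and Krt8 by -2.49 ± 0.29. Kdm4c (-1.43 ± 0.36, adjusted p = 0.11), Kdm4a (0.58 ± 0.13, adjusted p = 0.093) and Kdm4d (0.11 ± 0.18, adjusted p = 0.86) did not pass. Of the genes named here, Cdx2 alone kept its call with only these 2 groups in the fit, with array type as a block and without Jmjd2b knockdown array 2. The naive list was higher in the Jmjd2c knockdown (median 0.45, camera, adjusted p = 4.54e-08, and adjusted p = 0.187 with an estimated correlation), and the primed list (median -0.71; adjusted p = 3.98e-05, and adjusted p = 0.346 with an estimated correlation) and the imprinted list (median -0.44; adjusted p = 4.53e-07, and adjusted p = 0.187 with an estimated correlation) were lower. The glycolysis and hypoxia list did not differ by the test (median -0.02; adjusted p = 0.852). The call of the primed list was lost without Jmjd2c knockdown array 2, where its median was -0.25. Adjusted over the list alone, 7 naive genes were higher and 1 lower, 3 primed genes were lower and 5 imprinted genes were lower, against 1 higher, 1 lower and 1 lower over all genes.

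In all 11 of 26 lists were called between the knockdowns, 2 higher and 9 lower in the Jmjd2c knockdown. The other higher list was that of G2 and mitosis (median 0.16, 0 of 20 genes called and 1 higher adjusted over the list alone, camera, adjusted p = 4.28e-05, and adjusted p = 0.359 with an estimated correlation). Immediate early genes were lower (median -0.43, 1 of 17 called and 2 lower adjusted over the list alone, adjusted p = 2.94e-05, and adjusted p = 0.346 with an estimated correlation). Cholesterol synthesis genes had a median of -0.25 (0 of 18 called and 3 lower adjusted over the list alone, adjusted p = 2.94e-05, and adjusted p = 0.359 with an estimated correlation). The interferon list had a median of -0.16 (0 of 22 and 7 lower adjusted over the list alone, adjusted p = 9.00e-04, and adjusted p = 0.228 with an estimated correlation), and mesoderm genes -0.19 (0 of 19 and 4 lower adjusted over the list alone, adjusted p = 0.0011, and adjusted p = 0.346 with an estimated correlation). Neural genes had a median of -0.11 (2 of 18 lower and 4 lower adjusted over the list alone, adjusted p = 0.022, and adjusted p = 0.346 with an estimated correlation). For p53 targets it was -0.22 (0 of 20 and 0 adjusted over the list alone, adjusted p = 0.025, and adjusted p = 0.522 with an estimated correlation). For primitive endoderm it was -0.19 (0 of 22, with 1 higher and 4 lower adjusted over the list alone, adjusted p = 0.027, and adjusted p = 0.253 with an estimated correlation). Without Jmjd2c knockdown array 2 the calls of cholesterol, mesoderm and neural genes were lost, and without array 1 those of p53 targets and primitive endoderm. Without Jmjd2b knockdown array 3 the neural and p53 calls were lost. Neural genes also lost the call with the replicate block. The p53 median was 0.01 without Jmjd2c knockdown array 1. Leaving out single knockdown arrays gave medians between -0.25 and -0.03 for neural, between -0.30 and -0.08 for mesoderm, down to -0.32 for interferon, down to -0.37 for cholesterol and between -0.34 and -0.12 for primitive endoderm genes. With the mean of probe sets neural, p53 and primitive endoderm genes were not called, and with only the brighter genes mesoderm, p53 and primitive endoderm genes were not. The other lists were not called, with adjusted p between 0.066 for the stress list and 0.978.

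The number of differing genes was 2 with only these 2 groups in the fit and 4 with array type as a block, while within the array type that held both groups limma called 0 (1094 at an unadjusted p under 0.05). There the naive list had a median of 0.37, the primed list -0.62 and the imprinted list -0.44. The other called lists lay between -0.39 (immediate early) and 0.13 (G2 and mitosis). It was 145 with the replicate block and 142 with a pseudocount of 64. Leaving out arrays gave 35, 28 and 29 without controls 1, 2 and 3, 46 and 2 without Jmjd2b knockdown arrays 1 and 2, and 788 and 584 without Jmjd2c knockdown arrays 1 and 2.

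Most genes called in the Jmjd2c knockdown were also called in the Jmjd2b knockdown. There were 719 shared rises and 836 shared falls, 1555 genes in all, and 0 genes called in opposite directions. The 5 shared rises of largest mean size were those of Fgf5, Gbp2b, Igfbp3, Gbp2 and Myl9, and the 5 shared falls those of Nupr1, Slc11a1, Lrrc31, Camk2n1 and Tgm2 (-2.71 ± 0.34 and -2.81 ± 0.38, SE, in the Jmjd2b and Jmjd2c knockdowns). The shared genes were 89.7% of the Jmjd2c calls and 35.0% of the Jmjd2b calls. Independent lists of these lengths would share 89.7 rises and 123 falls. Unchanged groups simulated against the same controls shared 0, which says little, since unchanged groups are rarely called at all. Across genes, which are not independent replicates, the log2 changes correlated at r = 0.84, against a mean of 0.45 for the simulated groups, and their covariance was 0.198 against 0.0144, a difference of 0.184. The 3 controls cannot be split into sets of at least 2, so each way of dealing them out leaves 1 knockdown with 1 control array. In the 6 ways with no control array in common, a check chosen after the overlap was seen, the covariance lay between 0.162 and 0.204. These values argue against noise of the shared control arrays as the main source of the excess. A difference of the controls as a group stays open. Of the genes called in the Jmjd2b knockdown 85.6% changed by a smaller amount in the Jmjd2c knockdown, with median sizes of 0.69 and 0.46. Of the genes called in the Jmjd2c knockdown, 39.1% changed by a smaller amount in the Jmjd2b knockdown. Since the genes of each set were chosen on the value in the knockdown that called them, some shrinkage is built in. The shared count was 988 with array type as a block, 837 with only 2 groups in each fit, 426 without control array 3 and 772 without control array 1, and 462 with a 2-fold minimum.

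**Figure D3:**
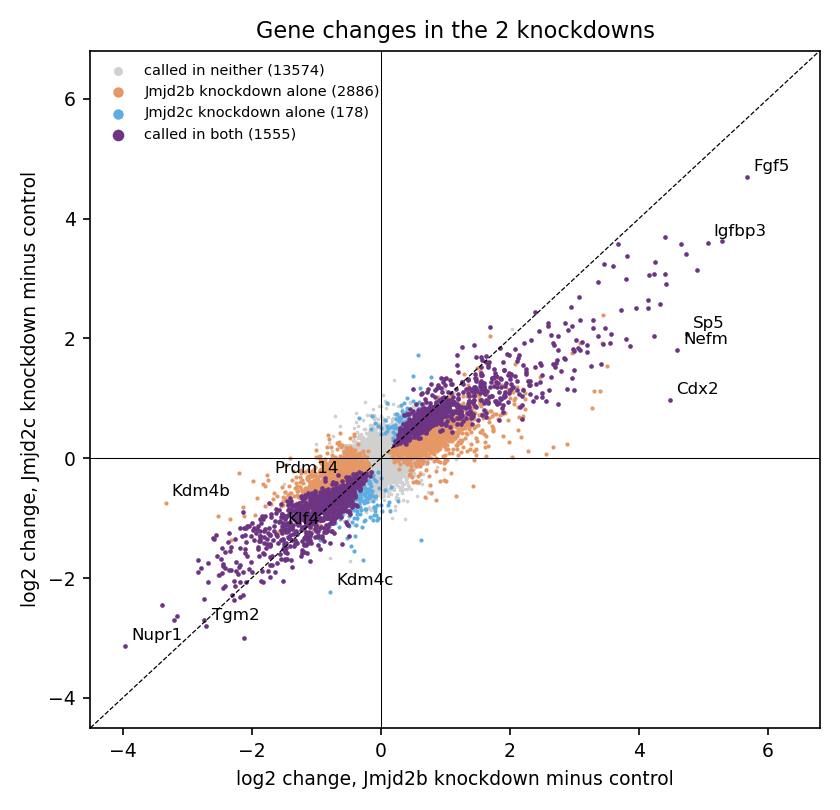
Log2 change against control in the Jmjd2b knockdown (x axis) and the Jmjd2c knockdown (y axis) for each of 18193 genes, coloured by where the gene passed the test, with the dashed line marking equal changes. The 1555 genes called in both lie in the upper right and lower left of the plot, and r across genes is 0.84.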

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

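The tests of the explanations below were chosen after the results they bear on had been seen, apart from the count of other splits of the arrays. Groups of 2 or 3 arrays are too small for a test of single outlying arrays.

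Probe sets that carry no gene symbol, or several, were left out of the report's comparisons. In a fit of all 45037 probe sets limma called 899 of these 10092 probe sets in the Jmjd2b knockdown (584 up, 315 down) and 230 in the Jmjd2c knockdown (120 up, 110 down). That is 8.91% and 2.28% of them, against 19.7% and 6.74% of the probe sets with 1 symbol.

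Of the genes called in the Jmjd2c knockdown 89.7% were also called in the Jmjd2b knockdown in the same direction, 1555 genes that made up 35.0% of the Jmjd2b calls. With no control array in common the changes still correlated across genes at 0.69 or more in the 6 ways of dealing out the controls, which argues against noise of the shared controls as the whole cause. With array type as a block 988 genes were shared, against 113 for independent lists, and after quantile normalization 1697. These counts argue against array type and array-wide scaling as the whole cause. The block did not part the sets of arrays marked out by identical values. No control lay in the set of the Jmjd2c knockdown arrays, so the block decides nothing about a difference between those sets, which stays open. A biological overlap of both enzymes stays open too. So does a lower level of each target in the other knockdown (56.6% and 57.3% of the control means). The same holds for any way in which the control cultures differed as a group. The design has no second control or second hairpin to separate these.

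The lists of glycolysis and hypoxia and of the stress responses had negative medians in both knockdowns. In the first list 15 of 23 genes fell in the Jmjd2b and 16 in the Jmjd2c knockdown. In the stress list 9 of 19 fell and 1 rose in the Jmjd2b knockdown, and 10 fell in the Jmjd2c knockdown. With an estimated correlation camera called neither list (adjusted p from 0.194 to 0.237). Leaving out each control array kept the medians of both lists in both knockdowns at -0.31 or below, and quantile normalization kept them at -0.345 or below, which argues against 1 deviating control array and against scaling. Control cultures that differed as a whole in oxygen, density or medium cannot be told apart from an effect of both hairpins: the knockdowns differed from each other by medians of -0.14 for the stress list and -0.02 for the glycolysis list, and no other control cultures were analysed here.

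Contractile genes such as Tagln (log2 changes 4.90 and 3.14) and Myl9 (4.73 and 3.41) rose in both knockdowns. Fibroblasts carried along with the cells would bring their other transcripts too, but the 13 of 21 markers dim in the controls, with Tagln and Acta2 left out, had median changes of 0.02 (SD 0.57 over genes) and 0.14 (SD 0.33). In the Jmjd2b knockdown 3 of the 13 rose, so these values argue against fibroblasts as the whole cause and leave a small share open. Tagln, an actin-binding protein, and Myl9, a myosin light chain, are not actin genes and have 1 probe set each, not of the shared kind. Their rises therefore argue against probe sets shared between actin relatives, for these genes. Leaving such probe sets out could not touch them, so their highest adjusted p there, 0.0104 (limma), decides nothing. For the actin genes that explanation stays open: Acta2 lost its rise without such probe sets (-0.02 and -0.09), while Acta1 and Actc1 were untouched. Cells of another type and a change of the ES cells themselves were not tested and stay open.

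For the Jmjd2b knockdown, 4441 genes were called with the real grouping. The highest count among the other splits of the 6 arrays into 3 and 3 was 0 (limma; up to 702 genes at an unadjusted p under 0.05). The real split is 1 of 10, which is too few for a share under 0.05. Every other split also mixed control and knockdown arrays on both sides. The difference between the real groups then enters the spread and lowers the calls by construction, so the counts of 0 say little. Of the 4 splits that part all 3 pairs of equal number, the 3 others called 0 genes each, with 233 to 347 at an unadjusted p under 0.05.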

How the results depend on the processing

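Array type as a block was chosen after seeing the data; the other alternatives were planned. Most causes of the differences below were not tested. A 2-fold minimum gives fewer genes by construction. Without either Jmjd2c knockdown array, the lone array left in that group adds nothing to the estimate of spread. Nor do these arrays enter when only the control and Jmjd2b knockdown are fitted. Higher counts in these fits therefore cannot be read as evidence about the array left out. Leaving out arrays gave higher as well as lower counts. The direction and call of Kdm4b in the Jmjd2b knockdown and of Kdm4c in the Jmjd2c knockdown held under all alternatives, and no alternative moved the median change of all genes by over 0.1.

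Of 203 called results of named genes 109 were called under every alternative, 93 lost the call in at least 1 and 2 reversed; of 46 uncalled ones 23 were called in at least 1. Of 35 called list results 19 kept the call under every alternative other than the estimated correlation, with which 0 were called.

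With a 2-fold minimum the counts were 1166 (Jmjd2b), 553 (Jmjd2c), 55 (between the knockdowns) and 462 (shared). With only the 2 groups compared they were 5612 (Jmjd2b), 874 (Jmjd2c), 2 (between) and 837 (shared). With array type as a block they were 3888, 1043, 4 and 988. Between the knockdowns the replicate block gave 145 and a pseudocount of 64 gave 142; the block moved no other count by over 1.5 times (4309 and 1378 genes for Jmjd2b and Jmjd2c).

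Leaving out 1 array gave 2624 to 5615 genes for Jmjd2b, 462 to 2919 for Jmjd2c, 2 to 788 between the knockdowns and 426 to 2206 shared. The lowest counts came without control 3, or without Jmjd2b knockdown 2 for the comparison of the knockdowns. The highest came without Jmjd2c knockdown 1, where the lone array of the Jmjd2c group added nothing to the estimate of spread. Kdm4b ranged from -3.60 to -3.09, Kdm4c from -3.04 to -1.42, the correlation from 0.74 to 0.86 and the called lists from 27 to 36.

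Reversed values were the mesoderm list in the Jmjd2b knockdown with only the brighter genes (-0.85), Kdm4a in the Jmjd2c knockdown with the mean of probe sets (0.15), and, without cross-hybridising probe sets, Hoxa5 (0.20) and Acta2 (-0.0155) in the Jmjd2b and Zfp352 (-0.13) and Acta2 (-0.0897) in the Jmjd2c knockdown. Leaving out arrays reversed uncalled values: Kdm4d (-0.185 to 0.0628, and -0.00202 to 0.226 between the knockdowns), Usp17la (-0.19 to 1.01), Tcstv1 (-0.361 to 0.0712), Tcstv3 (-0.230 to 0.0146) and Pou5f1 (-0.0217 to 0.0149). About 24% to 25% of probe sets lie under the pseudocount, where changes cannot be measured well.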

Other observations

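The genes of these 2 groups were picked after values had been seen, so their counts describe the genes and are no test of enrichment. Guanylate-binding proteins, related immunity GTPases and genes of antigen presentation were higher in the Jmjd2b knockdown: 15 of 18 rose and 0 fell, with a median log2 change of 1.42, and in the Jmjd2c knockdown 7 rose and 0 fell (median 0.81). Gbp3 rose by 4.41 and 3.07, Irgm1 by 4.41 and 3.70, Tapbp, a chaperone of antigen loading, by 2.35 and 0.96, and Irf1 by 1.57 and 1.25. In the interferon list fixed in advance Oas1a (-1.37 and -1.14) and Stat2 (-0.89 and -1.03) fell in the same arrays.

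Of 22 genes of the actin cytoskeleton and of contraction 19 rose and 0 fell in the Jmjd2b knockdown (median 1.68) and 13 rose and 0 fell in the Jmjd2c knockdown (median 0.82). Both counts hold Acta2 as a rise, whose value is uncertain. Tropomyosin Tpm1 rose by 2.98 and 1.82, zyxin (Zyx) by 2.74 and 1.65, and Ccn2, a matricellular gene, by 3.36 and 2.94.

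The medians of brighter genes per chromosome, over 9083 genes on the autosomes and X, lay between -0.07 and 0.06 in the Jmjd2b knockdown and between -0.08 and 0.02 in the Jmjd2c knockdown. An extra copy of a chromosome in all cells would shift a median towards 0.585 on the log2 scale.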
